A study of Mus musculus with 18 samples.

How the data were processed

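Poly(A)-selected RNA libraries from C57BL/6 mice were compared between Chd2+/- animals (HET) and wild-type animals (WT). The tissues were the medial ganglionic eminence (MGE) and the cortex at E13.5 and the hippocampus at P45. Each of the 6 groups held 3 libraries, and all 18 libraries of the series were used. The deposited table held raw counts per gene symbol, with no normalization, and its whole-number values, with column totals of 26841671 to 38802765 counts, matched that unit. The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.1.1, SAMtools and DESeq2 and the genome build mm10. The counting program, the gene annotation and the strand setting are not given in the sources used here.

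The table had 24062 lines with 24060 distinct symbols, of which 3700 lines had no count in any library. GENCODE M21 placed 22724 symbols on the genome, RefSeq placed a further 1184, and 152 were not placed. Symbols that had been turned into calendar dates filled 27 lines and held 0.247 to 0.297% of the counts of a library. They were kept in the totals and the tests, and no such gene is named. The 10 genes with the most counts took 3.26 to 4.71% of a library. Between replicates of a group, the squared difference per degree of freedom was 5.79 to 100.5 times that of counting noise over 18 pairs (genes with at least 20 counts), so no replicate was a copy of another.

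Genes were tested in each tissue separately with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a robust quasi-likelihood F test compared HET with WT on the deposited counts. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. Library-scaled counts (CPM) are TMM-normalised, and errors on CPM are SDs over 3 libraries. Differences of the genotype effect between tissues were tested as interaction contrasts in one fit of all 18 libraries. Pearson correlations of fold changes across genes left out Chd2.

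Gene lists for cell types, signalling pathways and cell functions of forebrain were written from general knowledge, together with lists for neighbouring tissues and blood. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists in MGE and cortex and 33 in hippocampus. Each test was repeated with an estimated correlation, and fry was run beside it. Camera compares a list with the other genes, while fry asks whether the members of a list move, on balance, one way. Many genes stand in more than 1 list.

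The tissues, tests, lists, thresholds and first set of alternatives were fixed before the data were examined. The same holds for the rule on named genes. It takes Chd2, then among genes past the threshold, with groups that do not overlap and a mean log2 CPM of at least 1, the 10 higher and the 10 lower genes with the largest change. Genes in the list of sex-linked genes and predicted gene names were excluded from these, while other genes on X or Y were kept. Where fewer than 5 genes passed, the 5 genes with the lowest p in each direction were taken instead. In MGE, where 7 genes passed, genes in the list of sex-linked genes were not counted toward that number, a reading settled after the data were seen. Up to 4 members were named for each list past the threshold, up to 2 for any other list described, and up to 5 genes for each interaction. A gene outside this rule is stated as chosen after its values were seen.

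The procedure was tested on simulated data built on the spread of each tissue. Of genes changed 2-fold, 74.6% were recovered in MGE (14406 genes), 53.6% in cortex (14478 genes) and 87.9% in hippocampus (15093 genes). For 1.5-fold changes the shares were 50.0%, 22.2% and 71.9%. Among the genes called, 8.86%, 6.14% and 12.9% had not been changed. All 20 simulated lists of 20 genes changed 1.3-fold were called in each tissue, and 1, 0 and 0 of 100 unchanged lists were called. Simulated genes varied independently of each other, so these counts do not show how often lists of correlated genes are called. In the data, the correlation estimated within a list reached 0.85 (cortex cell cycle genes).

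The alternatives were RLE and upper-quartile scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, one fit of all 18 libraries, the replicate number as a block, the level of Y-linked genes as a covariate, camera with an estimated correlation, and leaving out each library in turn. Alternatives on autosomal genes alone, without the sex-linked genes and without cortex HET 1 and HET 2 were added after seeing the data.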

Results

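Gene expression was measured by RNA sequencing in 18 mouse libraries, 3 WT and 3 Chd2+/- (HET) from each of 3 tissues, the embryonic MGE and cortex and the adult hippocampus. The tissues carried their own markers at the TMM-normalised level. Nkx2-1, a transcription factor that specifies the MGE, stood at 836 CPM in WT and 927 CPM in HET MGE, and at no more than 1.02 CPM in any other group. Lhx6, which marks interneurons born there, stood at 457 and 504 CPM in WT and HET MGE, 17.6 and 9.85 CPM in cortex, and 18.5 and 15.8 CPM in hippocampus. Emx1, a regulator of the dorsal forebrain, stood at 126 and 155 CPM in WT and HET cortex, 18.03 and 19.5 CPM in hippocampus, and 0.527 and 0.390 CPM in MGE. Neurod6, a marker of excitatory neurons, stood at 1117 ± 89.5 CPM (SD, n = 3) in WT and 710.3 ± 373 CPM in HET cortex. It stood at 254 and 279.6 CPM in WT and HET hippocampus and at 2.17 and 0.637 CPM in MGE. Camk2a and Mbp, a kinase of mature excitatory neurons and a myelin protein, reached 6156 and 3926 CPM in WT hippocampus and 5746 and 4556 CPM in HET hippocampus, against 51.1 CPM or less in the embryonic groups. The labels do not say whether the replicates are separate animals, so p-values measure only the spread between these samples.

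The first question was how far Chd2, a chromatin remodeller on chromosome 7 (73426638 to 73541830, mm10), was lower in each tissue of animals that carry one mutated copy. In MGE, Chd2 stood at 163 ± 10.5 CPM (SD, n = 3) in WT and 140.0 ± 4.22 CPM in HET. In cortex it stood at 148 ± 5.93 and 125 ± 0.233 CPM, and in hippocampus at 73.8 ± 4.18 and 65.3 ± 1.39 CPM. All 9 HET libraries lay below the 3 WT libraries of their tissue. The log2 fold changes were -0.24 (SE 0.09), -0.22 (SE 0.08) and -0.17 (SE 0.06). As a single gene tested in 3 tissues, Chd2 had an adjusted p of 0.0235 in each, and over all genes its adjusted p was 0.980, 0.578 and 0.191. The single-gene test no longer passed 0.05 without MGE WT 3 (log2 fold change -0.18), MGE HET 1 (-0.23), cortex WT 2 (-0.20), cortex WT 3 (-0.23) or hippocampus WT 3 (-0.14), nor in cortex with the Y-linked level as a covariate (-0.21). Tests of the difference of the Chd2 effect between tissues gave adjusted p of 1.00 for MGE against cortex, 0.914 for MGE against hippocampus and 0.812 for cortex against hippocampus.

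**Figure D1:**
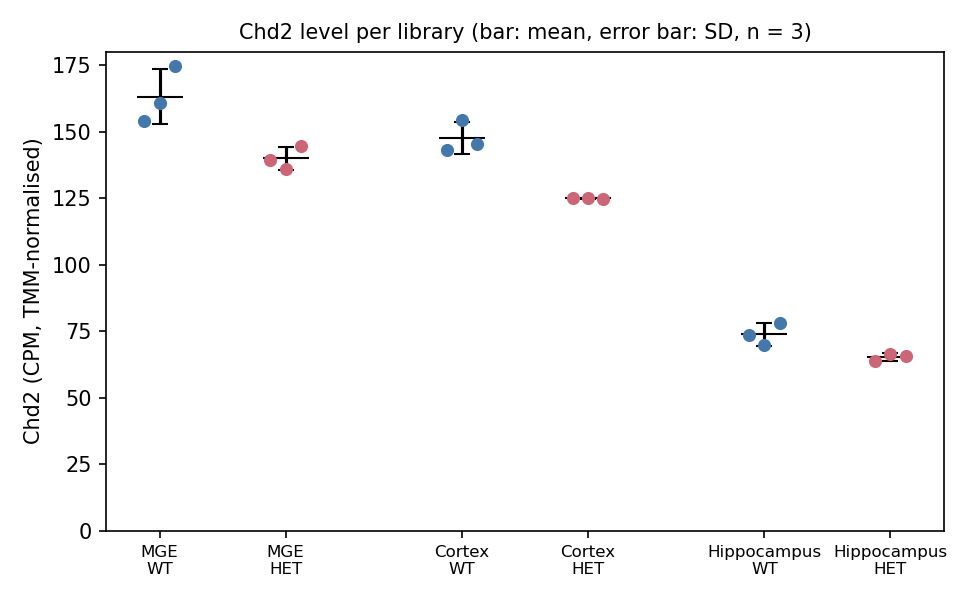
Chd2 level in TMM-normalised CPM (vertical axis, from 0) for each of the 18 libraries, by tissue and genotype (horizontal axis), with WT in blue and HET in red, the mean as a bar and the SD as an error bar (n = 3). In each tissue the 3 HET libraries lie below the 3 WT libraries, with means of 140.0 against 163 CPM in MGE, 125 against 148 in cortex and 65.3 against 73.8 in hippocampus.

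In the MGE, the genes that passed the test within the tissue lay on the sex chromosomes. Ddx3y, Uty, Eif2s3y and Kdm5d, which are carried by the Y chromosome, stood at 53.7, 29.2, 62.6 and 85.0 CPM in HET and at 0.0386 CPM or less in WT, and Uba1y at 0.871 ± 0.0769 CPM against 0. Xist, the RNA that silences one X chromosome in females, stood at 0.799 ± 0.293 CPM in HET and 1798 ± 105 CPM in WT. Kdm6a, an X-linked histone demethylase whose second copy escapes that silencing, fell from 85.3 ± 2.48 to 51.5 ± 1.40 CPM (log2 fold change -0.73, SE 0.08, adjusted p = 0.0101). These 7 genes, 5 higher and 2 lower, were all that passed among 14624 tested, and 0 autosomal genes passed (lowest adjusted p 0.334). With edgeR, 659 genes (4.51%) had an unadjusted p under 0.05. At the adjusted threshold limma-voom called 7 genes and DESeq2 called 36, of which 29 were lower and 28 lay outside X and Y. The WT and HET values did not overlap in 9.85% of genes, where chance gives 10%. Xist was high in the 3 WT MGE libraries (1737 to 1919.8 CPM) and the 4 Y-linked genes summed to 212 to 259.6 CPM in the 3 HET libraries, so genotype and these markers split the MGE libraries in the same way. Without WT 1 the test called 27 genes, and without HET 1 or HET 2 it called 11. Kdm6a missed the threshold without WT 2 (adjusted p = 0.0937), WT 3 (0.0789) or HET 3 (0.141), and Uba1y without WT 2 (0.0937), WT 3 (0.0789), HET 2 (0.0789) or HET 3 (0.214). In one fit of all 18 libraries 0 of these 7 genes passed, with an adjusted p of 0.251 for Kdm6a and Uba1y. That fit called 5 other genes, all lower and all outside X and Y, among them Aldoc and Eomes (adjusted p = 0.0157 for both) and Neurog2 (0.0297). It shares the spread over all groups, and Eomes, scaled over all libraries, stood at 1.41 CPM in WT MGE against 362 CPM in WT cortex.

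**Figure D2:**
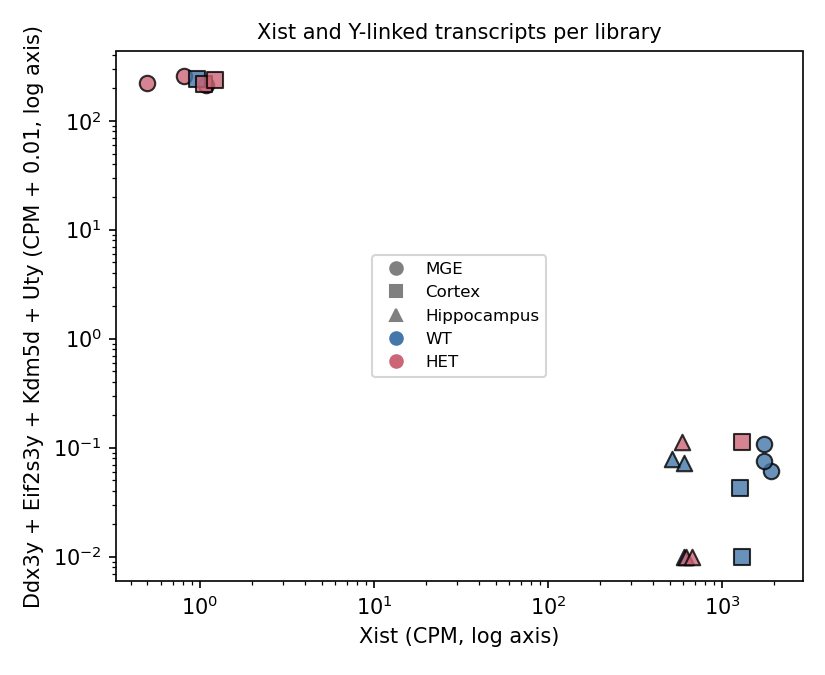
Xist level (horizontal, CPM, log axis) against the summed level of Ddx3y, Eif2s3y, Kdm5d and Uty (vertical, CPM plus 0.01, log axis) in each of the 18 libraries, with shape for tissue and colour for genotype. All 3 MGE WT libraries lie at high Xist and all 3 MGE HET libraries at high Y-linked level, and all 6 hippocampus libraries lie at high Xist (518 to 672 CPM). Both cortex groups hold both kinds, so the 3 libraries of a cortex group did not all come from the same animal.

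Among the MGE genes that did not pass, those with the lowest p were the following. Myo7a, an unconventional myosin, had a log2 fold change of 0.69 (SE 0.16, adjusted p = 0.827). Values for Atp13a4, Firre and Col15a1 were 1.53 (SE 0.36), 0.45 (SE 0.11) and 0.75 (SE 0.21). Eomes, a marker of cortical intermediate progenitors, had -2.60 (SE 0.46, adjusted p = 0.334), with 1.44 CPM in WT and 0.232 CPM in HET. Eif2s3x, an X-linked translation factor, had -0.59 (SE 0.11), Kitl, the ligand of the receptor Kit, -0.61 (SE 0.12) and Aldoc, a glycolytic enzyme of glia, -0.97 (SE 0.20).

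A set of 3 gene groups was lower in HET MGE than the other genes. Of 14 astrocyte genes, 11 were below zero, with a median log2 fold change of -0.49 (adjusted p = 1.13e-07, but adjusted p = 0.198 with an estimated correlation). None of them passed over all genes, and 7 were lower when adjusted over the list alone, among them Aldoc (-0.97, SE 0.20), Mlc1 (-0.90, SE 0.18), the glutamate transporter Slc1a3 (-0.53, SE 0.12) and Aldh1l1 (-1.13, SE 0.26). Which cells of the embryonic MGE expressed these genes was not tested. The radial glia list did not pass (15 of 23 below zero, median -0.08, adjusted p = 0.280), with 0 past the threshold over all genes and 1 lower when adjusted over the list alone. Of 19 cortical projection neuron genes, 13 were below zero with a median of -0.14 (adjusted p = 6.63e-04, but adjusted p = 0.884 with an estimated correlation). In that group 0 passed over all genes and 3 were lower when adjusted over the list alone, with Nfib at -0.51 (SE 0.11), Nfix at -0.73 (SE 0.16), Neurod2 at -2.53 (SE 0.63) and Neurod6 at -1.77 (SE 0.68). Neurod6 stood at 0.408, 2.66 and 3.43 CPM in the 3 WT libraries and at 0.515 to 0.702 CPM in HET, so WT 1 lay below each HET library. Neurod2 stood at 0.510, 1.17 and 2.69 CPM in WT and at 0.167 to 0.365 CPM in HET. In WT cortex Neurod6 and Neurod2 stood at 1117 and 315 CPM, so both lay near the floor in MGE. Which cells they came from there was not tested. Of 18 genes of the lateral ganglionic eminence and striatum, 15 were below zero with a median of -0.41 (adjusted p = 0.00259, but adjusted p = 0.884 with an estimated correlation). There, 0 passed over all genes and 0 when adjusted over the list alone, and Rxrg stood at -1.35 (SE 0.60), Penk at -0.80 (SE 0.43), Foxp1 at -0.30 (SE 0.16) and Ppp1r1b at -0.88 (SE 0.48). The last group missed the threshold without WT 2 (adjusted p = 0.206) or HET 2 (0.248). In place of 3 lists, the test called 5 without WT 1, 6 without WT 3, 12 without HET 1 and 14 without HET 2.

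The genes that specify MGE interneurons did not differ as a group. Of 28, 15 were above and 13 below zero with a median of 0.01 (adjusted p = 0.756), with 0 past the threshold over all genes or adjusted over the list alone, Cxcr4 at -0.38 (SE 0.17) and Gbx1 at 1.35 (SE 0.62). Of 44 cell cycle genes, 27 were above zero with a median of 0.02 (adjusted p = 0.630) and 0 passed over all genes or adjusted over the list alone, with E2f1 at 0.22 (SE 0.11) and Nusap1 at -0.20 (SE 0.11).

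In the cortex no single gene passed the test, while whole groups of genes stood apart from the rest. Cell cycle genes were higher in HET (43 of 44 above zero, median log2 fold change 0.40, adjusted p = 1.84e-12, but adjusted p = 0.645 with an estimated correlation). Among them were the thymidylate synthase Tyms (0.38, SE 0.13), the cyclins Ccnd1 (0.72, SE 0.24) and Ccne1 (0.78, SE 0.26) and the replication clamp Pcna (0.28, SE 0.10). Neuronal differentiation genes were lower (22 of 24 below zero, median -0.21, adjusted p = 5.51e-04, but adjusted p = 0.659 with an estimated correlation), with the neuronal transcription factor Myt1l at -0.52 (SE 0.24), the adhesion molecule Cntn2 at -0.59 (SE 0.27) and the microtubule protein Dcx at -0.43 (SE 0.20). HET 3 stood apart from the other HET libraries on both groups. The mean cell cycle level, as log2 deviation, was 0.40 and 0.44 in HET 1 and HET 2, -0.27 in HET 3, and -0.26, -0.10 and -0.20 in the 3 WT libraries. The neuronal level was -0.33, -0.29 and 0.26 in the HET libraries and 0.08, 0.07 and 0.21 in WT.

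**Figure D3:**
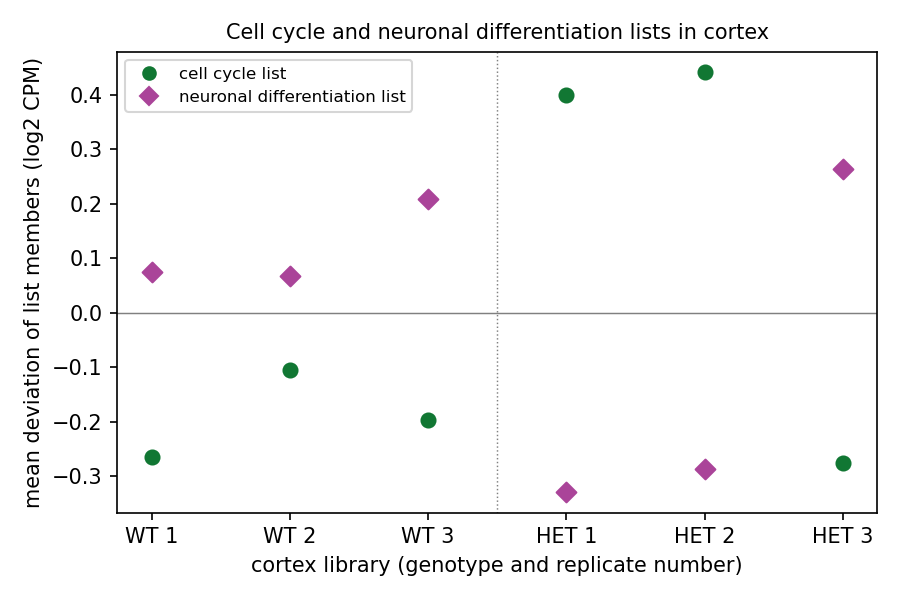
Mean level of the 44 cell cycle genes (circles) and the 24 neuronal differentiation genes (diamonds) in each cortex library, as deviation from the mean of the 6 libraries (vertical axis, log2 CPM), by genotype and replicate number (horizontal axis). HET 1 and HET 2 lie at 0.40 and 0.44 for cell cycle and -0.33 and -0.29 for neuronal genes, while HET 3 lies at -0.27 and 0.26.

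Single genes in the cortex did not pass (0 of 14757 with edgeR, lowest adjusted p 0.107 for Hddc3). With edgeR, 1165 genes (7.89%) had an unadjusted p under 0.05, and at the adjusted threshold DESeq2 called 8 and limma-voom 0. The groups did not overlap in 11.4% of genes, where chance gives 10%. Without HET 3 the same test called 4598 genes, 2654 higher and 1944 lower, and without WT 1 it called 1. One fit of all 18 libraries called 4, among them Hddc3 and Myo7a (adjusted p = 0.0145 for both) and Tdp2 (0.0340). Hddc3, which encodes a nucleotide hydrolase, had a log2 fold change of -1.58 (SE 0.15), with 32.4 ± 2.63 CPM in WT and 10.8 ± 1.72 CPM in HET. Sox4, a transcription factor of young neurons, had -0.47 (SE 0.10), with 874.5 ± 33.1 and 632 ± 46.8 CPM. Adamtsl3, the guidance receptor Epha3 and Klhl24 had -1.44 (SE 0.28), -0.73 (SE 0.16) and -0.40 (SE 0.09). Myo7a had 1.13 (SE 0.16) and Tdp2, a DNA repair enzyme, 0.80 (SE 0.12). The replication histones Hist1h2ae and Hist1h3c had 1.12 (SE 0.21) and 1.11 (SE 0.22), and Alg8, a glycosylation enzyme, had 0.58 (SE 0.12). All of these but Hddc3 had an adjusted p of 0.578. Hddc3, Adamtsl3, Alg8 and Myo7a lie on chromosome 7, as Chd2 does, and Tdp2, Sox4, Hist1h2ae and Hist1h3c lie on chromosome 13. The replication histone list as a whole did not pass (45 genes, median 0.16, adjusted p = 0.390), and 2 of its members were higher when adjusted over the list alone against 0 over all genes.

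Camera called 20 of 34 lists in the cortex, 7 higher and 13 lower, and 0 with an estimated correlation. In each of the 20, 0 members passed over all genes and 0 when adjusted over the list alone. Genes of Cajal-Retzius cells and the cortical hem were higher (17 of 20 above zero, median 0.31, adjusted p = 7.80e-04, but adjusted p = 0.645 with an estimated correlation), with Ebf2 at 1.32 (SE 0.39), Wnt8b at 1.13 (SE 0.37), Trp73 at 0.44 (SE 0.17) and Ebf3 at 0.47 (SE 0.18). Notch pathway genes were higher (22 of 24, median 0.26, adjusted p = 0.00106, but adjusted p = 0.659 with an estimated correlation), with the effectors Hey1 at 0.64 (SE 0.23), Heyl at 0.64 (SE 0.24) and Hey2 at 0.83 (SE 0.31). Wnt pathway genes were higher (28 of 34, median 0.29, adjusted p = 0.00256, but adjusted p = 0.659 with an estimated correlation), with Tcf7 at 0.56 (SE 0.24) and Rspo1 at 0.99 (SE 0.46). Histone H3.3 and chromatin genes were higher (20 of 25, median 0.15, adjusted p = 0.00956, but adjusted p = 0.694 with an estimated correlation), with the histone chaperone Asf1b at 0.52 (SE 0.19) and Suz12, a Polycomb subunit, at 0.49 (SE 0.20). HET 3 went against HET 1 and HET 2 on these pathways. Mean levels in HET 1, HET 2 and HET 3 were 0.33, 0.30 and -0.22 for the Notch pathway. They were 0.22, 0.32 and -0.0975 for the Wnt pathway and 0.19, 0.18 and -0.17 for histone H3.3. In WT 1, WT 2 and WT 3 they were -0.13, -0.03 and -0.25 for Notch, 0.18, -0.19 and -0.43 for Wnt, and -0.12, -0.02 and -0.07 for histone H3.3. For Cajal-Retzius and hem genes they were 0.30, -0.48 and -0.45 in WT and 0.16, 0.49 and -0.02 in HET. WT 1 thus lay above HET 1 and HET 3 on that list.

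Markers of blood and of tissues beside the cortex were tested as lists. Meninges and mesenchyme genes were higher (15 of 23, median 0.20, adjusted p = 0.0115, but adjusted p = 0.694 with an estimated correlation), with the matrix genes Lum at 0.72 (SE 0.20) and Col3a1 at 0.71 (SE 0.21). The groups overlapped on the mean level of this list, at 0.44, -0.48 and -0.22 in WT and -0.29, 0.18 and 0.37 in HET. WT 1 had the highest level of all. Red blood cell genes were higher (6 of 8, median 0.82, adjusted p = 0.0249, but adjusted p = 0.645 with an estimated correlation), with the embryonic globins Hba-x at 1.79 (SE 0.51) and Hbb-y at 1.12 (SE 0.38). Hbb-y stood at 766 and 989 CPM in HET 1 and HET 2, 325 CPM in HET 3 and 239 to 397 CPM in WT. Microglia and macrophage genes were lower (17 of 19, median -0.22, adjusted p = 0.0261, but adjusted p = 0.725 with an estimated correlation), with C1qb at -0.38 (SE 0.26). Choroid plexus genes had a median of -1.52 with 14 of 15 below zero, 0 past the threshold over all genes or adjusted over the list alone, and did not pass as a list (adjusted p = 0.0625), with Aqp1 at -1.61 (SE 0.74) and Folr1 at -2.03 (SE 1.11). Ttr, the most abundant choroid plexus transcript, varied within both groups, with 846 ± 748 CPM in WT, where WT 2 had 0.420 CPM, and 209.8 ± 202 CPM in HET.

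Genes of neurons and synapses made up most of the lower lists of the cortex. Voltage-gated channel genes were lower (35 of 43, median -0.23, adjusted p = 2.05e-05, but adjusted p = 0.645 with an estimated correlation), with the calcium channels Cacna1e at -0.66 (SE 0.18) and Cacna1i at -0.71 (SE 0.22) and the potassium channel Kcnq3 at -0.94 (SE 0.30). Glutamate receptor genes were lower (28 of 39, median -0.26, adjusted p = 3.38e-04, but adjusted p = 0.645 with an estimated correlation), with Grin2b at -1.09 (SE 0.26) and Gria2 at -0.56 (SE 0.15), subunits of NMDA and AMPA receptors. Presynaptic release genes (26 of 31, median -0.17, adjusted p = 0.00135) and GABA receptor genes (19 of 21, median -0.25, adjusted p = 0.00156) were lower, both with an adjusted p = 0.645 with an estimated correlation. Bsn, a scaffold of the active zone, stood at -0.33 (SE 0.11). MGE interneuron genes were lower (17 of 23, median -0.36, adjusted p = 0.00290), as were adult interneuron genes (15 of 23, median -0.36, adjusted p = 0.00643), cortical projection neuron genes (15 of 21, median -0.15, adjusted p = 0.00541), hippocampal excitatory genes (17 of 25, median -0.30, adjusted p = 0.0182) and axon guidance genes (27 of 45, median -0.09, adjusted p = 0.0429). For these groups the adjusted p = 0.645 with an estimated correlation. Named members were Zeb2 (-0.47, SE 0.14), Erbb4 (-0.79, SE 0.38) and Dlx2 (-0.82, SE 0.42) for MGE interneurons, Cck (-0.98, SE 0.38) and Kcnc2 (-1.33, SE 0.53) for adult interneurons, Sox5 (-0.58, SE 0.19) for projection neurons, Pou3f1 (-0.92, SE 0.33) for hippocampal excitatory neurons, and Nrp1 (-0.42, SE 0.12) and Sema3c (-0.58, SE 0.20) for axon guidance. Lhx6 stood at 5.40 and 4.11 CPM in HET 1 and HET 2, 20.04 CPM in HET 3 and 14.02 to 21.6 CPM in WT, and Neurod6 at 514.5, 475.5 and 1141.0 CPM in the 3 HET libraries. Oxidative phosphorylation genes (55 of 71, median -0.11, adjusted p = 7.80e-04, but adjusted p = 0.725 with an estimated correlation) and ribosomal protein genes (59 of 76, median -0.07, adjusted p = 0.0182, but adjusted p = 0.739 with an estimated correlation) were lower, with Uqcr11 at -0.28 (SE 0.10) and Rps4l at -0.21 (SE 0.11).

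Of the 20 cortex lists, 9 passed without each library in turn and 11 did not. Without WT 1, adjusted p was 0.0806 for histone H3.3, 0.126 for axon guidance and 0.720 for microglia. Leaving out WT 2 gave 0.0693 for projection neurons, 0.0665 for red blood cells, 0.282 for meninges and 0.0542 for ribosomal proteins, and leaving out WT 3 gave 0.0665 for the Wnt pathway. With HET 1 left out it was 0.125 for adult interneurons, 0.0874 for hippocampal excitatory, axon guidance and oxidative phosphorylation genes, 0.157 for histone H3.3, 0.562 for microglia and 0.807 for ribosomal proteins. With HET 2 left out it was 0.0835 for histone H3.3 and red blood cells, 0.0719 for axon guidance, 0.142 for microglia, 0.487 for ribosomal proteins and 0.111 for oxidative phosphorylation. With HET 3 left out it was 0.0701 for axon guidance and 0.376 for meninges. Without both HET 1 and HET 2, an alternative chosen after seeing the data, the HET group is HET 3 alone. Its direction on the cell cycle (lower) and neuronal differentiation genes (higher) follows from that choice. In that fit the direction reversed for 12 lists. The mean level in HET 1, HET 2 and HET 3 was -0.17, -0.13 and 0.21 for ribosomal proteins. For oxidative phosphorylation it was -0.19, -0.19 and 0.23. With the Y-linked level as a covariate the meninges list missed the threshold (0.131), and with upper-quartile scaling axon guidance (0.0557) and microglia (0.0529) did. One fit of all 18 libraries gave 0.0524 for projection neurons, 0.131 for axon guidance, 0.0595 for red blood cells and 0.0673 for meninges.

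In the adult hippocampus, 40 genes rose and 124 fell in HET among 15283 tested. Tmem163, a zinc-binding membrane protein of synaptic vesicles, fell the most, from 107.8 ± 10.7 to 11.5 ± 1.13 CPM (log2 fold change -3.23, SE 0.09, adjusted p = 2.97e-09). It lies on chromosome 1 (127486546 to 127679548). Lgr6, a receptor for R-spondins, fell from 12.5 ± 2.92 to 1.69 ± 0.170 CPM (-2.89, SE 0.19). Lgr6 lies on chromosome 1 too (134983301 to 135105276). Whether the falls of Tmem163 and Lgr6 are independent of each other was not tested. Fabp7, a fatty acid binding protein of radial glia and astrocytes, rose from 9.62 ± 0.977 to 25.6 ± 1.79 CPM (1.42, SE 0.10, adjusted p = 2.98e-05). Arntl, the transcription factor at the centre of the circadian clock, rose from 26.3 ± 0.959 to 44.8 ± 0.833 CPM (0.77, SE 0.06). By the naming rule, all 3 HET libraries lay on one side of all 3 WT libraries in each named gene.

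Other genes that rose were the secreted signal Wnt9a (1.02, SE 0.16), the lipopolysaccharide-binding protein gene Lbp (0.81, SE 0.17), the myelin gene Opalin (0.76, SE 0.13), the lipoprotein lipase Lpl (0.75, SE 0.13), the potassium channel Kcna4 (0.75, SE 0.09), the cyclooxygenase Ptgs2 (0.70, SE 0.10), the ubiquitin ligase Fbxo32 (0.66, SE 0.08) and Filip1 (0.65, SE 0.12). Genes that fell were the transcription factor Gata2 (-1.36, SE 0.22), Mid1 (-1.34, SE 0.22), the astrocyte enzyme Etnppl (-1.14, SE 0.17), the small heat shock protein Hspb1 (-1.09, SE 0.19), the adhesion molecule Kirrel2 (-1.07, SE 0.11), the melanocortin receptor Mc4r (-1.07, SE 0.15) and the endothelial transcription factors Sox17 (-1.06, SE 0.22) and Sox18 (-1.02, SE 0.18). Of the 20 named genes, Tmem163, Lgr6, Fabp7, Arntl, Kcna4, Ptgs2, Fbxo32 and Kirrel2 passed without each library in turn, and the other 12 missed the threshold without at least 1. Without WT 1 the adjusted p was 0.0587 for Opalin and 0.0786 for Mid1. Leaving out WT 2 gave 0.243 for Lbp, 0.244 for Lpl, 0.120 for Filip1, 0.1004 for Gata2, 0.132 for Mid1, 0.0545 for Etnppl, 0.234 for Sox17 and 0.0998 for Sox18. Leaving out WT 3 gave 0.108 for Lbp, 0.103 for Lpl, 0.117 for Mid1, 0.0617 for Hspb1 and 0.0602 for Sox17. For HET 1 the values were 0.118 for Lbp, 0.0881 for Opalin, 0.0940 for Lpl, 0.0842 for Mid1 and 0.106 for Sox17, and for HET 2 they were 0.106 for Mid1, 0.0677 for Hspb1 and 0.0564 for Sox18. For HET 3 they were 0.0621 for Wnt9a, 0.263 for Lbp, 0.116 for Opalin, 0.0738 for Lpl, 0.172 for Filip1, 0.0904 for Gata2 and Sox18, 0.0709 for Etnppl, 0.148 for Hspb1, 0.0575 for Mc4r and 0.216 for Sox17. With other settings Mid1 (0.0535) and Sox17 (0.0561) missed it with upper-quartile scaling, Lpl (0.0740) and Mid1 (0.0928) without a filter, and Lbp (0.0686) and Sox17 (0.0620) with limma-voom. In one fit of all 18 libraries, 5 of the 20 passed (Tmem163, Lgr6, Fabp7, Arntl and Lpl) and 15 did not. These were Wnt9a (0.741), Lbp (1.00), Opalin (0.607), Kcna4 (0.703), Ptgs2 and Fbxo32 (0.597), Filip1 and Etnppl (0.657), Gata2 (0.238), Mid1 (0.673), Hspb1 (0.305), Kirrel2 (0.0564), Mc4r (1.00), Sox17 (0.0828) and Sox18 (0.177).

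**Figure D4:**
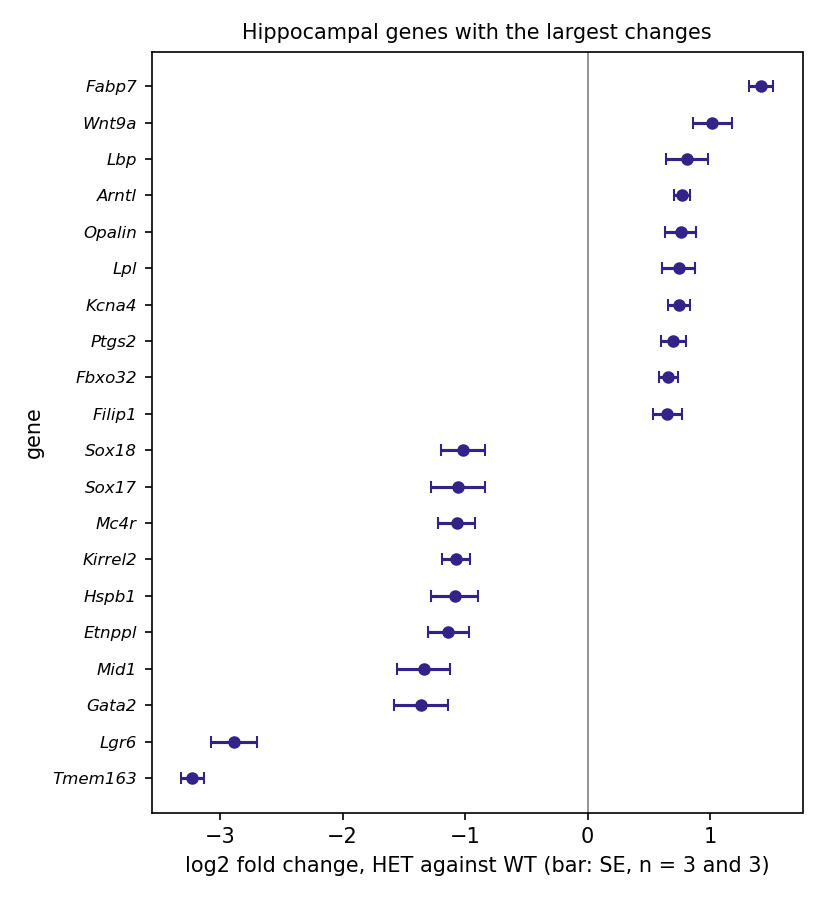
Log2 fold change of HET against WT (horizontal axis) with its SE as error bar (3 libraries against 3) for the 10 higher and the 10 lower named hippocampal genes (vertical axis). Fabp7 lies highest at 1.42, and Tmem163 and Lgr6 lie lowest at -3.23 and -2.89.

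Of the 164 genes, 159 lay on autosomes and 4 on X or Y, and all 6 libraries were Xist-high. The groups did not overlap in 20.8% of genes, where chance gives 10%, and 2378 genes (15.6%) had an unadjusted p under 0.05. Without HET 3 the test called 23 genes, 21 of them among the 164, and without WT 2 it called 37, with 36 shared. Without WT 1 it called 292, with 144 shared, and without HET 2 it called 71 higher and 82 lower. DESeq2 called 435 genes, no filter on low counts 291 and one fit of all 18 libraries 11, and with upper-quartile scaling 76 were lower and 48 higher. The 11 included Arntl and the clock genes Per2, Per3 and Tef, chosen after their values were seen.

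Genes of blood vessels fell as a group. Of 22, 21 were below zero with a median log2 fold change of -0.37 (adjusted p = 1.55e-12, and adjusted p = 0.0484 with an estimated correlation). In all, 7 fell over all genes and 14 when adjusted over the list alone, among them the VEGF receptor Flt1 (-0.81, SE 0.07), the lipid transporter of the blood-brain barrier Mfsd2a (-0.79, SE 0.09), Ly6c1 (-0.59, SE 0.09) and the efflux pump Abcb1a (-0.53, SE 0.08). The mean level of the list was -0.16, -0.19 and -0.22 in the HET libraries and 0.20, 0.21 and 0.15 in WT. This list also passed with fry (adjusted p = 0.00187), and no other list did in any tissue. The lowest fry adjusted p of the other lists was 0.0756 in MGE (astrocyte), 0.481 in cortex and 0.115 in hippocampus (Notch pathway).

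Stress response genes were lower (16 of 20 below zero, median -0.22, adjusted p = 8.75e-07, but adjusted p = 0.702 with an estimated correlation). Over all genes 3 fell, and 10 were lower when adjusted over the list alone. Herpud1, which acts in degradation at the endoplasmic reticulum, stood at -0.41 (SE 0.07), Hspb1 at -1.09 (SE 0.19), Creld2 at -0.57 (SE 0.12) and Xbp1, a transcription factor of the unfolded protein response that missed the threshold, at -0.46 (SE 0.10). Ribosomal protein genes were higher (71 of 77, median 0.10, adjusted p = 1.72e-10, but adjusted p = 0.743 with an estimated correlation), with 0 higher over all genes or adjusted over the list alone, Rps15a at 0.16 (SE 0.05), Rps3 at 0.15 (SE 0.05), while Rps4l fell over all genes and over the list alone (-0.65, SE 0.09). Oxidative phosphorylation genes were higher (68 of 72, median 0.07, adjusted p = 5.20e-07, but adjusted p = 0.743 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone, and Ndufb4 at 0.20 (SE 0.06) and Uqcrh at 0.15 (SE 0.05).

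Oligodendrocyte genes were higher (18 of 20, median 0.21, adjusted p = 0.00294, but adjusted p = 0.743 with an estimated correlation). Opalin rose, 2 genes were higher and 1 lower when adjusted over the list alone, Aspa stood at 0.48 (SE 0.11) and Cspg4, a proteoglycan of oligodendrocyte precursors, fell (-0.59, SE 0.08). Choroid plexus genes were higher (9 of 12, median 0.45, adjusted p = 0.0459, but adjusted p = 0.743 with an estimated correlation), with 0 past the threshold over all genes and 4 higher when adjusted over the list alone, and Otx2 at 2.00 (SE 0.54) and Enpp2 at 0.43 (SE 0.11). HET 1 and HET 3 were high on both lists, at 0.31 and 0.15 for oligodendrocytes and 0.46 and 0.30 for choroid plexus, while HET 2 lay at -0.18 on both. The oligodendrocyte list missed the threshold without WT 3 (adjusted p = 0.142) or HET 1 (0.384), and the choroid plexus list without WT 1 (0.0985), WT 3 (0.126), HET 1 (0.321) or HET 3 (0.0716), with upper-quartile scaling (0.0964), with no filter (0.159) and in one fit of all 18 libraries (0.686).

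Glutamate receptor genes were lower (30 of 40, median -0.11, adjusted p = 0.00497, but adjusted p = 0.702 with an estimated correlation, and 0.171 in one fit of all 18 libraries). Of these, 0 fell over all genes and 5 were lower and 2 higher when adjusted over the list alone, with the postsynaptic scaffolds Shank2 at -0.29 (SE 0.08) and Homer1 at -0.38 (SE 0.10), while Grm3, a metabotropic receptor, rose (0.39, SE 0.08). Notch pathway genes were lower (19 of 24, median -0.17, adjusted p = 0.0104, but adjusted p = 0.471 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone, Lfng at -0.39 (SE 0.11) and Numbl at -0.21 (SE 0.06). Immediate early genes were lower (20 of 28, median -0.22, adjusted p = 0.0104, but adjusted p = 0.743 with an estimated correlation). Fosb fell (-0.74, SE 0.12) and Ptgs2 rose, 8 were lower and 1 higher when adjusted over the list alone, and Klf4 stood at -0.73 (SE 0.19). That list missed the threshold without WT 2 (adjusted p = 0.395), WT 3 (0.0557) or HET 1 (0.161).

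**Figure D5:**
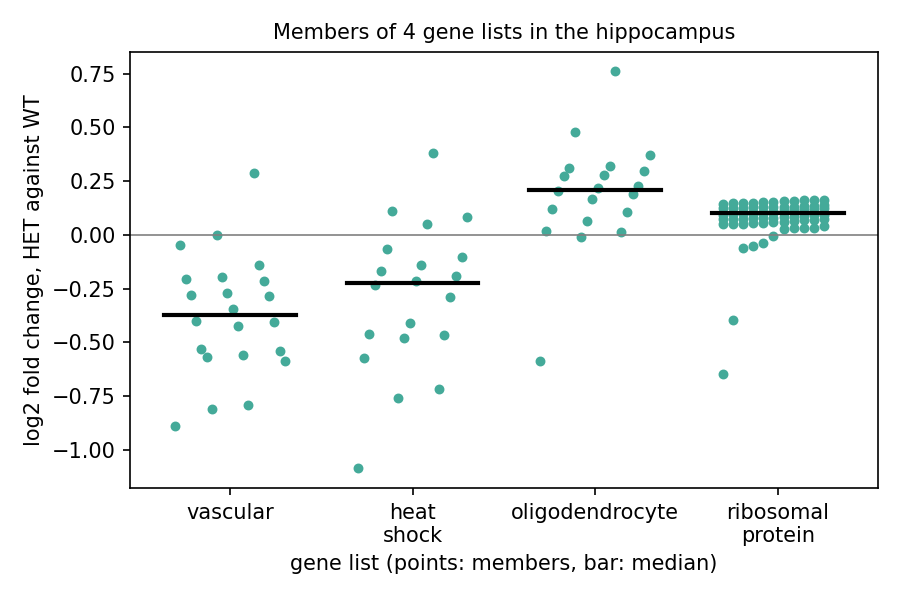
Log2 fold change of HET against WT (vertical axis) for each tested member (points) of 4 gene lists in the hippocampus (horizontal axis), with the median as a bar. The medians are -0.37 for vascular, -0.22 for heat shock and stress, 0.21 for oligodendrocyte and 0.10 for ribosomal protein genes.

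The tissues were then compared with each other. Tmem163 was the gene whose genotype effect differed between tissues by the largest test value. Its log2 fold change was 0.13 (SE 0.28) in MGE, 0.09 (SE 0.22) in cortex and -3.23 (SE 0.22) in hippocampus in the joint fit, and the difference was 3.36 (SE 0.35, adjusted p = 4.96e-04) for MGE and 3.32 (SE 0.31, adjusted p = 9.90e-05) for cortex. Lpl differed between cortex and hippocampus, with -0.53 (SE 0.13) and 0.74 (SE 0.13) and a difference of -1.27 (SE 0.18, adjusted p = 0.0176). Among 16125 genes, edgeR called 0 for MGE against cortex, 1 for MGE against hippocampus and 2 for cortex against hippocampus, with 1130, 1187 and 2071 genes at an unadjusted p under 0.05. DESeq2 called 14, 37 and 76. Next by p, none past the threshold, were Eomes (-2.48, SE 0.39), Aldoc (-1.12, SE 0.18), Chrna7 (1.05, SE 0.19), Neurog2 (-1.97, SE 0.38) and Lpl (0.95, SE 0.19) for MGE minus cortex. For MGE minus hippocampus they were Eomes (-2.64, SE 0.44), Slitrk2 (-0.86, SE 0.14), Fabp7 (-1.82, SE 0.31) and Arntl (-1.01, SE 0.18), and those for cortex minus hippocampus included Eng (1.59, SE 0.27) and Nid1 (1.43, SE 0.25). Genotype and sex markers coincide in the MGE libraries, so contrasts with MGE hold both. Without cortex HET 3, 1044 genes differed for MGE against cortex and 2791 for cortex against hippocampus. MGE against cortex gave 6 without MGE WT 1 and 3 without MGE HET 2, and MGE against hippocampus gave 7 and 12 without these and 2 without hippocampus WT 3. Cortex against hippocampus gave 10 without cortex WT 1, 9 without cortex WT 2 and 4 without hippocampus HET 2. It gave 3 without hippocampus WT 1 and 1, Tmem163, without each of 5 others, where Lpl missed the threshold. Its adjusted p was 0.0911 without cortex HET 1, 0.0635 without cortex HET 2, 0.113 without hippocampus WT 2, 0.108 without hippocampus WT 3 and 0.0614 without hippocampus HET 3.

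With no call in cortex and only X- and Y-linked calls in MGE, shared calls between tissues were not informative. Of the hippocampal genes, 54 of 150 (36%) had the same sign in MGE and 56 of 153 (36.6%) in cortex. The same-sign share over all genes was not computed. These shares therefore do not show that the hippocampal genes differ from other genes. Across genes, which are not independent replicates, the log2 fold changes of MGE and cortex had a Pearson correlation of 0.177 (Spearman 0.207, 14203 genes). It was -0.0608 (Spearman -0.151, 14050 genes) for MGE and hippocampus and -0.144 (Spearman -0.145, 14161 genes) for cortex and hippocampus. Without single libraries, MGE and cortex gave 0.402 (cortex WT 1 left out), 0.103 (cortex HET 1) and 0.0919 (MGE WT 3). MGE and hippocampus gave -0.0307 (MGE WT 1), -0.0232 (MGE HET 1), -0.109 (MGE HET 2), -0.0226 (MGE HET 3) and -0.0164 (hippocampus HET 2), and cortex and hippocampus gave -0.0857 (cortex WT 1). With genes of at least 10 CPM in both tissues, MGE and hippocampus gave -0.131.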

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

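The genes in this part were singled out by the test of the difference between tissues, which was chosen before its result was seen, as were the splits given beside it. Tmem163 had a genotype effect that differed by 3.36 on the log2 scale between MGE and hippocampus and by 3.32 between cortex and hippocampus. Lpl had a genotype effect that differed by -1.27 between cortex and hippocampus, a call lost without each of cortex HET 1 (adjusted p 0.0911), cortex HET 2 (0.0635), hippocampus WT 2 (0.113), hippocampus WT 3 (0.108) and hippocampus HET 3 (0.0614). Of 100 drawn splits of the genotype labels within tissues, 15 called as many genes as the real one for MGE against hippocampus (1, highest other 6) and 17 for cortex against hippocampus (2, highest other 337). Labels were drawn in each tissue separately, so some draws keep the hippocampus grouping or its mirror and can call Tmem163 again. A share under 0.05 was hence hard to reach. These splits cannot decide whether chance explains the counts. For MGE against cortex the real split called 0 genes with edgeR (1130 at an unadjusted p under 0.05, DESeq2 14), which all 100 must match, so the splits say nothing on it, with 2187 as the highest other. Splits that call 337 or 2187 genes show that other groupings of these samples can call more genes than genotype. What sets these splits apart was not tested.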

How the results depend on the processing

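Leaving out HET 1 and HET 2 of the cortex, the autosomal genes alone and the correlations without sex-linked genes were chosen after the results were seen. The cause was not tested for any difference below unless stated. RLE scaling left the counts of genes and lists and the correlations on the same side of their limits in each tissue.

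DESeq2 called 29 lower genes in MGE, 5 higher and 3 lower in cortex, 110 higher and 325 lower in hippocampus, and 14, 37 and 76 genes for MGE against cortex, MGE against hippocampus and cortex against hippocampus. Without a filter on low counts there were 1 lower gene in cortex and 75 higher and 216 lower in hippocampus, and upper-quartile scaling gave 76 lower in hippocampus. One fit of all 18 libraries called 0 higher and 5 lower genes in MGE (0 of the 7 shared, 0 on X or Y), 2 and 2 in cortex and 4 and 7 in hippocampus (10 of 164 shared). With the replicate number as a block, MGE had 1 lower gene, Chd2 at -0.23 and no longer past 0.05, and adjusted p of 0.191 for Kdm6a and 0.196 for Uba1y. Hippocampus had 19 higher and 61 lower genes (66 of 80 shared) and lost Lbp (0.0869), Opalin (0.116), Lpl (0.0847) and Hspb1 (0.0707), and cortex against hippocampus had 1 gene, without Lpl (0.117). In none of the 3 tissues did every sample correlate best with its own number. Among autosomal genes alone MGE had 0 higher and 0 lower with edgeR. The Y-linked level as a covariate gave Chd2 at -0.21 in cortex. It was not run in MGE, where it follows genotype (correlation 1.00), or in hippocampus, where it hardly varies (log2 range 0.27). With an estimated correlation camera called 0 lists in MGE, 0 in cortex and 1 in hippocampus. The correlation of MGE and hippocampus was -0.131 with at least 10 CPM and -0.151 by Spearman.

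Without cortex HET 1 and HET 2 the HET group held HET 3 alone, assumed to vary like WT, and chosen with its list levels already seen. Then 1 gene was lower and 11 lists passed. The direction reversed for cell cycle (adjusted p 0.00218), neuronal differentiation (5.80e-04), adult interneuron (0.420), GABA receptor (0.521), presynaptic (0.249), histone H3.3 (0.00173), Notch (0.0341), Wnt (0.717), microglia (0.0613), red blood cell (0.912), ribosomal (3.49e-24) and oxidative phosphorylation genes (7.85e-16).

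Leaving out each library in turn gave 4 to 10 higher and 1 to 17 lower genes and 3 to 14 lists in MGE, 0 to 2654, 0 to 1944 and 13 to 19 in cortex, and 7 to 77, 16 to 215 and 6 to 10 in hippocampus. Chd2 ran from -0.28 to -0.18, -0.27 to -0.20 and -0.21 to -0.14. Genes that differed between tissues ran from 0 to 1044 (MGE against cortex), 1 to 12 (MGE against hippocampus) and 1 to 2791 (cortex against hippocampus). The highest counts of the first and last came without cortex HET 3. Correlations ran from 0.0919 to 0.402, -0.109 to -0.0164 and -0.169 to -0.0857. Over all alternatives together, 201 hippocampal and 15 MGE values of named genes kept direction and threshold and 59 and 11 missed it. For lists these were 212 and 56 in cortex (and the 12 reversed above), 87 and 21 in hippocampus and 31 and 5 in MGE. In simulated data at this depth and spread, 22.2% of 1.5-fold changes in cortex were recovered.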

Other observations

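The tests of sex, of genotype on Xist, of the cortex libraries, of genotype acting on the clock and of position were chosen after the results were seen.

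In MGE, 7 of 7 genes past the threshold lay on X or Y. A difference of embryo sex between the groups is a candidate explanation of these calls. Groups of equal sex are argued against by the levels in all 3 WT and 3 HET libraries. Xist stood at 1737 to 1920 CPM in WT and at 1.08 CPM or less in HET. The summed Y-linked genes stood at 0.0973 CPM or less in WT and at 212 to 260 CPM in HET. Genotype setting these levels is argued against by 5 of the 12 cortex and hippocampus libraries, which had levels of the other genotype's kind. Any effect of Chd2 in MGE, on the astrocyte list too, is confounded with this difference. The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 7 genes (1 split as many, highest other 6) and 3 lists (10 splits as many, highest other 18). Groupings other than genotype can thus call more lists at the preset correlation, and the cause of this was not tested.

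In cortex, cell cycle genes were higher and neuronal genes lower in HET 1 and HET 2, and HET 3 went the other way. A WT sample deposited as HET 3 is argued against by its Chd2 level, -18.5 CPM relative to the lowest WT library. Genotype moving the lists alike in all HET libraries was not seen. An uneven developmental stage and an effect of genotype that varies between embryos, or is masked in HET 3 by another difference, stay open and cannot be told apart. The lowest HET cell cycle level, at -0.17 relative to the highest WT level, and the 1 HET library outside the pattern are the observation itself, and the labels give the same stage for all cortex libraries. The splits are too few for a share under 0.05, with 20 lists in the real one (1 as many, highest other 18). A count of 0 genes with edgeR is matched by any split (10 as many, highest other 8), so the splits say nothing on it (1165 at an unadjusted p under 0.05, DESeq2 8, limma-voom 0).

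In hippocampus, Arntl rose and the clock genes Per3 (-0.87, SE 0.14), Ciart (-0.80, SE 0.15), Tef (-0.43, SE 0.06), Bhlhe40 (-0.52, SE 0.08) and Bhlhe41 (-0.60, SE 0.09), chosen after their values were seen, fell. In clock genes not yet looked up, the median of 4 genes in phase with Arntl exceeded that of 6 in antiphase by 0.58, past the 0.3 set before (0.24 in cortex and 0.08 in MGE). The gap came from the antiphase genes (median -0.53), since the median in phase was 0.05, Cry1 (-0.53, SE 0.15) went against its phase, Nr1d1 stood at -0.04 (SE 0.06), and none of the 10 passed within the tissue (lowest adjusted p 0.0591, Hlf), while Per2 did in one fit of all 18 libraries (0.0469). Collection at different times of day may explain this. Genotype acting on the clock cannot be told apart from it, since 0 of the 6 hippocampus libraries have a collection time in the labels. Whether collection time bears on the other hippocampal genes and lists was not tested. The splits are too few for a share under 0.05, with 164 genes (1 as many, highest other 0) and 9 lists (4 as many, highest other 14).

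Other genes that fell in hippocampus, chosen after their values were seen, were the endothelial genes Eng (-0.91, SE 0.10), Robo4 (-0.82), Nid1 (-0.84) and Acvrl1 (-0.69) and the chaperones Pdia4 (-0.62, SE 0.11), Hyou1 (-0.46) and Dnajc3 (-0.38).

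Correlations as far from 0 came from 11 of 100 pairs of splits for MGE and cortex (0.177, highest other 0.436), 21 for MGE and hippocampus (0.0608, highest other 0.153) and 8 for cortex and hippocampus (0.144, highest other 0.203), so chance is not excluded.

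Of 375 cortex genes within 30 Mb of Chd2, 10 (2.67%) had an unadjusted p under 0.01, against 0.653% elsewhere (Fisher exact adjusted p 0.00938 over 60 regions), and of 571 on chromosome 13, 15 (2.63% against 0.625%, adjusted p 6.41e-04) did. In MGE it was 5 of 370 (Fisher exact adjusted p 0.733) and in hippocampus 18 of 389 (0.868). Of the named cortex genes, Hddc3, Adamtsl3, Alg8 and Myo7a lie within 30 Mb of Chd2. Tdp2, Sox4, Hist1h2ae and Hist1h3c lie on chromosome 13. An effect of position and an effect of lower Chd2 were not told apart for these genes. In the joint fit Hddc3 stood at -1.59 in cortex and -0.02 (SE 0.22) in hippocampus, where Chd2 was lower too. Myo7a stood at 1.11 in cortex and 0.035 (SE 0.15) in hippocampus. Neither difference passed the interaction test (adjusted p 0.135 and 0.158). In MGE, Myo7a stood at 0.69 (SE 0.16) and did not pass.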
